A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

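Expression was measured on 4 one-colour Agilent arrays, 1 per sample, from 2 groups of S. pombe cells, S2A white (2 arrays) and S7A pink (2 arrays). Per the labels' protocols, a single colony was grown in YES at 30 °C, total RNA was extracted with acidic phenol-chloroform, and 200 ng of RNA was labelled with Cy3. Groups and replicate numbers were taken from the sample titles. The labels number the replicates but do not say that they came from separate cultures, so p-values measure only the spread between these arrays, which may be technical.

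Per the file headers, the authors scanned the arrays and extracted spot intensities with Agilent Feature Extraction 10.7.3.1, with spatial detrending of the background. The deposited processed intensity is linear, background-subtracted and not normalized between arrays, per the file headers. The deposited raw mean intensity and local background intensity of each spot were used for an alternative. The deposited flags for spots well above background, saturated or outlying (0 or 1, another kind of value) were used for filters. The authors' value table holds linear intensities in 5589 entries, 1 per probe, scaled so that the 75th percentile of each array is 2500. Its column medians were 944, 943, 957 and 952. It tracked the scanner values of the same array with a correlation of at least 0.999, so its scale and direction are settled, and the software that made it is not given in the sources used here. It was used as an alternative.

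Values were log2 processed intensities minus the array's 75th percentile over non-control spots. Control spots and spots with an outlier flag (214 and 288 on the S2A arrays, 238 and 256 on the S7A arrays) were left out. Spots of 1 probe were averaged: 4030 probes had 3 spots, 1484 had 2 and 15 had 10. A gene was tested if more than 0.5 of its spots were well above background on both arrays of at least 1 group, which kept 4893 genes and left out 636. Two-group linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Every adjusted p of a gene comes from limma. Where a gene was not well above background on either array of a group, a fold is a lower bound, written as at least N-fold. The bright group's mean log2 value was set against the mean, per array, of the higher of the dim probe's value and the lowest value among probes well above background. No fold is given where that bound was under 1. Bounds hold for the deposited background subtraction only: for all 24 genes named by the rule below with a bound, the fold with normexp was smaller than it.

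Before the data were examined, 38 gene lists, the alternatives and the rule for naming genes were fixed. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives. With an estimated correlation, camera judges a list against the few residual degrees of freedom of 4 arrays, so almost no list could pass. A failure in that setting alone therefore does not show that a list's call came from correlation between its genes. Where the estimate lay above the preset 0.01, the p at the preset may still be too small. Camera sets a list against the other genes, whereas fry asks whether its genes moved one way on balance, so their counts answer different questions. Of the 38 lists, 33 could be tested. The patterns for pericentromeric names, mitochondrial genes and antisense names matched no probe, and ade6 alone and the 2 telomere-linked helicases were too few for a set test. The pattern for small nuclear and nucleolar RNAs matched only 4 protein genes. Named genes were ade6 and rpb1, the 12 largest increases and 12 largest decreases among genes past the threshold whose groups did not overlap, and up to 4 members with the lowest p from each list that passed and from 10 lists on silencing, mating and markers. Genes named outside this rule were chosen after their values were seen: the purine, phosphate and further heterochromatin, RNAi and mating genes, hsp and subtelomeric examples beyond it, and the genes of the closing section. Groups did not overlap for 83.4% of genes, against 33.3% by chance.

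Gene symbols were taken from a RefSeq table of assembly ASM294v3 through the systematic identifiers, 5396 of 5529 of which matched; the others keep the array's name. Coordinates are those of the array annotation, whose header names an NCBI build of 2002. Near-identical copies, such as Tf2 elements, telomere-linked helicases, mating-type cassettes and centromeric repeats, can hybridise to the same probe and are uncertain as single genes. Whether the labelling kept strand for antisense features was not tested.

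Replicate arrays were compared with the spread between spots of a probe. The variance of the difference between replicates was 1.22 times the spot variance for S2A and 0.988 times for S7A, against 31.6 between an S2A and an S7A array. A further test, chosen after this spread was seen, asked whether a difference between replicates repeated across separate spots of a probe. Across genes, the differences seen by 2 spots had a Pearson correlation of 0.192 for S2A (4664 genes) and 0.201 for S7A (4853 genes), and a Spearman correlation of 0.292 and 0.349. A first run limited to brighter probes gave higher Pearson correlations and was replaced by this one over all probes above background. By the variance ratio only S2A exceeded the spread between spots, whereas the differences repeated in part across spots in both groups. Separate labellings of 1 RNA would also give such correlations. The replicates were counted as 2 samples as the titles number them. The number of arrays limits the precision. The procedure was tested on simulated data for the S7A pink against S2A white comparison, with 4893 genes and 200 changed. At log2 changes of 0.2, 0.5, 1 and 2 it recovered 15.1%, 68.9%, 92.6% and 100% of the changed genes, and 4.2% of the calls were false. In the data 60.6% of genes were called, far more than were changed here. The simulated noise was independent and held no effect of array position or shared RNA. These rates are therefore not those of the real calls. Alternatives covered background, scaling, the value table, filters, variance model, replicate block, each array left out, thresholds and the set test.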

Results

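Total RNA was profiled from fission yeast (Schizosaccharomyces pombe) carrying alanine substitutions in the C-terminal domain (CTD) of Rpb1, the largest subunit of RNA polymerase II. The CTD is a tail of repeated short peptides whose serines are phosphorylated during transcription. In the S2A mutant the serine at the second position of the repeat was replaced by alanine, and in the S7A mutant the serine at the seventh position. The series concerns silencing of an ade6+ reporter inserted in the heterochromatin beside centromere 1, which the submitters read from colony colour: red colonies mark a silenced reporter, and both mutants gave a mixture of pink and white colonies. The 4 arrays came from 2 groups, white S2A cells (2 arrays) and pink S7A cells (2 arrays), grown in the rich medium YES at 30 °C to exponential phase. Wild type, pink S2A cells and white S7A cells were not analysed here, so genotype and colony colour changed together in the one comparison that could be made. A difference is given as S7A pink relative to S2A white, and does not tell which mutant departed from wild type.

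Each array held 15744 spots, of which 15208 measured 5529 genes with 1 probe per gene and 536 were controls. On the S2A white arrays 4866 and 4695 genes were well above background, and on the S7A pink arrays 4865 and 4897. No spot was saturated. The median signal was 240 and 233 units on the S2A arrays and 254 and 224 units on the S7A arrays, beside a median local background of 27, 27, 28 and 27 units. Replicate arrays agreed closely, with a Pearson correlation across genes of 0.998 for S2A and 0.999 for S7A. The SD of the log2 difference between replicates was 0.16 for S2A and 0.11 for S7A, whereas between an S2A and an S7A array it was 0.71 and the correlation was 0.951 to 0.952. Genes are not independent replicates, so these correlations carry no p-value. At least 2-fold apart were 17 genes between the S2A replicates, 4 between the S7A replicates and 443 to 454 between arrays of different groups.

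The first question was whether the ade6 transcript, the readout of the colour assay, differed between the groups. The ade6 signal (SPCC1322.13, chromosome 3, 1316337 to 1317995) was 0.41 ± 0.06 (SD, n = 2) on the S2A arrays and 0.52 ± 0.01 (SD, n = 2) on the S7A arrays, as log2 relative to each array's 75th percentile. The difference of 0.11 log2 had a 95% interval of -0.01 to 0.23 and did not pass the threshold (limma, adjusted p = 0.098); with a variance trend the adjusted p was 0.049. The probe sums the reporter and any copy at the native ade6 locus, so it does not isolate the centromeric copy. Of the 12 purine synthesis genes, 7 were higher and 2 lower in S7A, with the same counts adjusted over the list alone; ade7 was 3.35-fold and ade8 2.21-fold higher. The list as a whole did not pass (camera, adjusted p = 0.076). The rpb1 probe was not well above background on any of the 4 arrays, so the level of the mutated gene's transcript could not be compared. Its level would not show the substitutions in any case.

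Centromeric non-coding RNAs were higher in S7A pink cells, with 1 exception among those tested. Of the 12 genes with the largest fitted increases, 7 were annotated as centromeric non-coding RNAs. SPNCRNA.371 (chromosome 2, 1636393 to 1636776) was 43.6-fold higher in S7A (log2 difference 5.45 ± 0.14 SE, adjusted p = 4.67e-05) and SPNCRNA.373 (chromosome 2, 1640114 to 1641543) 42.0-fold higher. SPNCRNA.234 (chromosome 1, 3786105 to 3787136) was 20.5-fold higher. SPNCRNA.360 was 67.1-fold higher, but stood well above background on only 1 of the 2 S2A arrays. SPNCRNA.231, SPNCRNA.372 and SPNCRNA.359 were not well above background on either S2A array and were at least 46.6-fold, 13.8-fold and 11.1-fold higher in S7A. The array annotation lists 23 centromeric non-coding RNAs, a group formed after the values were seen because the names fixed beforehand matched no probe. Of these, 12 were tested, 11 were higher in S7A and 1 was lower: SPNCRNA.483 on chromosome 3, with a log2 difference of -1.18. The remaining 11 were not tested, since in neither group did they stand well above background on both arrays. Of the 12, 7 passed this filter through S7A alone, which favours a higher value there. Of the 5 well above background on all 4 arrays, SPNCRNA.232, SPNCRNA.234, SPNCRNA.371 and SPNCRNA.373 were higher and SPNCRNA.483 was lower. The median fitted difference of the 12 was 4.50 log2, or 3.63 with the dim RNAs at their bounds, and 4.35 over the 5 measured on all 4 arrays. With the normexp background the fitted median was 1.96, or 3.49 over those 5, with 11 again higher. The single folds also shrank with normexp, to log2 differences of 4.44 for SPNCRNA.371, 4.40 for SPNCRNA.373, 3.49 for SPNCRNA.234, 4.15 for SPNCRNA.360, 3.46 for SPNCRNA.231, 2.14 for SPNCRNA.372, 1.78 for SPNCRNA.359 and -0.46 for SPNCRNA.483.

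Both telomere-linked helicase genes and both mating-type genes that were tested from the mat region shared that direction. All of them passed the filter through S7A alone, so their direction was close to fixed by it. The helicase genes tlh1 (chromosome 1, 1 to 5662) and tlh2 (chromosome 2, 4526885 to 4532644) were not well above background on either S2A array and were at least 6.78-fold and 9.90-fold higher in S7A (limma, adjusted p = 0.000244 and 0.000239). Near-identical copies of these genes lie at several chromosome ends, so the signals cannot be assigned to 1 of them. The mat1-Mc transcript (chromosome 2, 2114482 to 2115027), which encodes a minus-type regulator, was at least 12.3-fold higher, and matPc, which encodes a plus-type regulator, at least 2.06-fold higher. Each has a further copy in the silent mating-type region, so these probes do not separate the expressed from the silent copy. With the normexp background mat1-Mc differed by 2.14 log2, matPc by 0.52, tlh1 by 1.24 and tlh2 by 1.58, all under their bounds.

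**Figure D1:**
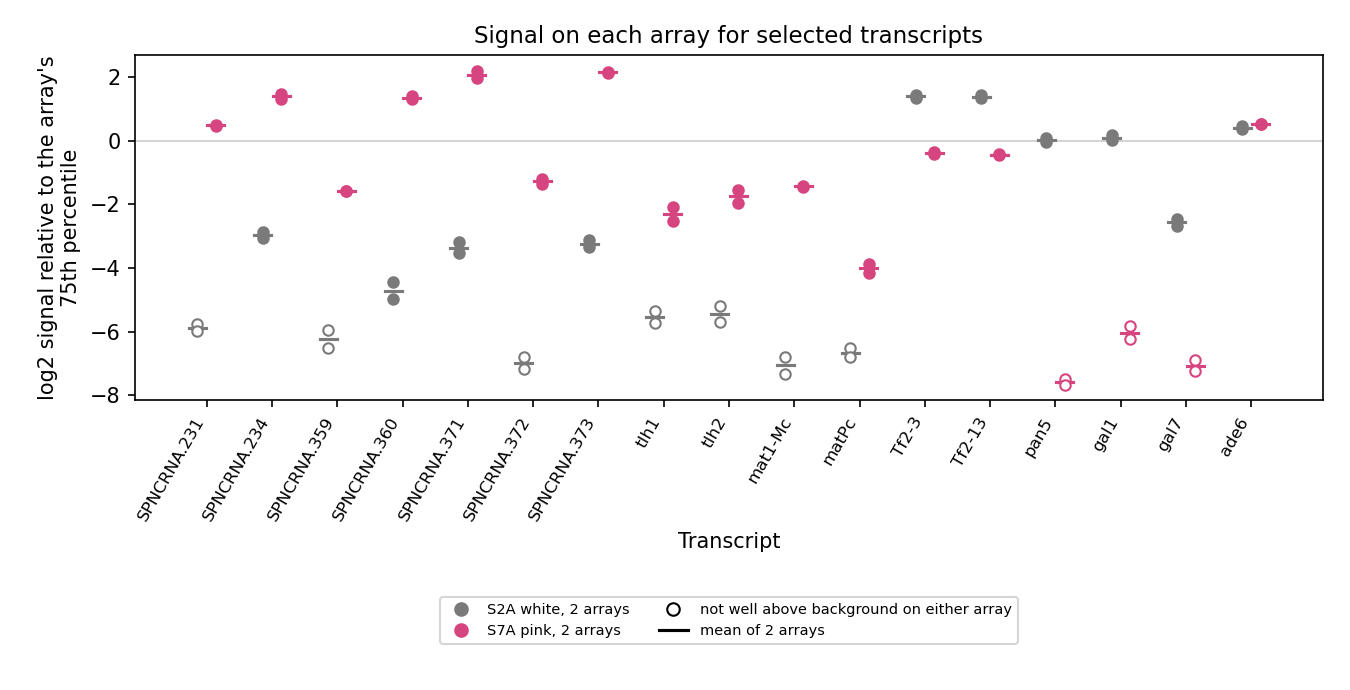
Signal of 17 transcripts on each array, as log2 relative to the array's 75th percentile (vertical axis), for S2A white (grey, 2 arrays) and S7A pink (pink, 2 arrays), with lines at the means and open circles where neither array was well above background. The 7 centromeric RNAs, tlh1, tlh2, mat1-Mc and matPc lie higher in S7A, the Tf2 elements, pan5, gal1 and gal7 lie lower, and ade6 differs by 0.11.

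The subtelomeric genes as a group went the other way. Of the 69 tested members of this list, 45 were lower in S7A, 11 were higher and 13 did not pass (47 lower and 11 higher when adjusted over the list alone), with a median log2 difference of -0.63. The list passed camera with its preset correlation (adjusted p = 0.000127). It did not pass with an estimated correlation (adjusted p = 0.552), where almost no list could. That estimate, 0.151, was above the preset 0.01, so correlation between the genes may have made the preset p too small. SPBPB10D8.01, a predicted cysteine transporter gene near the left end of chromosome 2, was 7.76-fold lower in S7A (log2 difference -2.96, and -1.45 with the normexp background). SPAC212.04c at the left end of chromosome 1 was at least 4.29-fold lower (log2 -0.72 with normexp). Among the 11 that were higher besides tlh1 and tlh2, aes1 was 9.64-fold and urh1 5.75-fold higher (log2 2.59 and 1.34 with normexp); both were named after their values were seen.

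Most of the largest fitted decreases lay in 1 block at the right end of chromosome 2. Of the 12 genes with the largest fitted decreases, 10 belonged to the SPBPB2B2 genes and the non-coding RNA among them, between 4458010 and 4504944. All 10 were dim in S7A, so their ranks rest on signal near background. The bound of gal10, 3.79-fold, lies under the 7.76-fold decrease of SPBPB10D8.01, which was measured in both groups. Of the 21 genes on the array in this interval, 12 were tested and all 12 were lower in S7A, and 11 of them were not well above background on either S7A array. Those 11 passed the filter through S2A alone, so their direction was close to fixed by it. The untested genes of the interval did not stand well above background on both arrays of either group. The pantothenate-pathway gene pan5 was at least 58.2-fold lower in S7A (adjusted p = 1.96e-05), the galactokinase gene gal1 at least 61.2-fold and SPNCRNA.532 at least 55.9-fold. The galactose genes gal7 and gal10 were at least 9.66-fold and 3.79-fold lower. The permease gene SPBPB2B2.01 (nrg1) was at least 17.6-fold lower, and SPBPB2B2.06c, whose probe shares sequence with SPAC1039.02, at least 26.6-fold. These bounds hold for the deposited background subtraction: with normexp the log2 difference was -3.25 for pan5, -3.33 for gal1, -1.27 for gal7 and -0.71 for gal10, all past the threshold. On its centromere-proximal side, the phosphate genes pho1 and pho84 were 2.15-fold and 2.05-fold higher in S7A. Outside the block, 34 subtelomeric genes were lower, 11 higher and 13 did not pass, among 58 tested. This block was delimited after its values were seen. SPBC557.05, an arrestin gene in the arm of chromosome 2, completed the 12 largest fitted decreases and was at least 5.80-fold lower (log2 -0.88 with normexp).

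**Figure D2:**
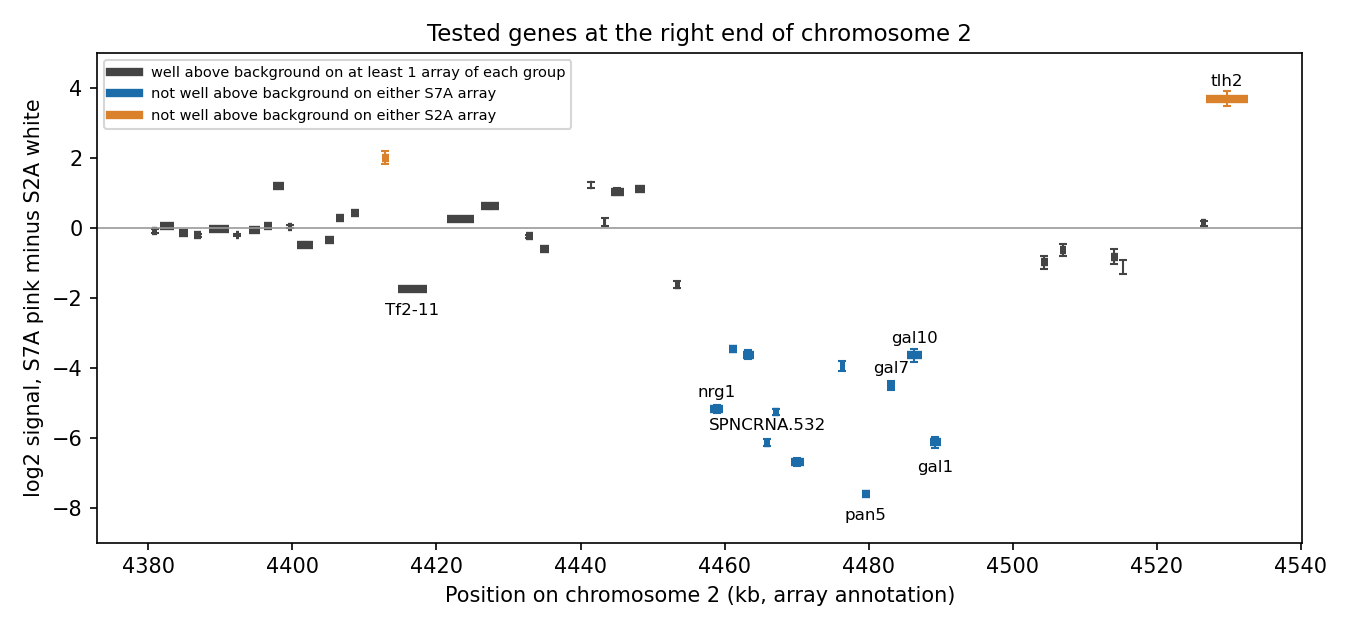
Fitted log2 difference, S7A pink minus S2A white (vertical axis), of the 42 tested genes at the right end of chromosome 2 against position in kb (horizontal axis); bars span each gene and whiskers show 1 SE. Blue genes were not well above background on either S7A array, so their fitted values are not bounds, and orange genes on neither S2A array; the blue run ends before SPBPB2B2.19c, at -0.98.

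Tf2 retrotransposons, the mobile elements of this genome, were lower in S7A pink cells by a similar amount at each probe. All 6 tested elements were lower, also when adjusted over the list alone, with a median log2 difference of -1.79 and a range from 3.32-fold (Tf2-7) to 3.60-fold (Tf2-10). Their probes share sequence, so the 6 values are close to repeated measurements of the family rather than of 6 elements. The list passed camera with its preset correlation (adjusted p = 0.000536). It did not pass with an estimated correlation (adjusted p = 0.552), where almost no list could. That estimate, 0.834, was far above the preset 0.01, so the preset p treats repeated measurements as nearly independent genes and is likely too small.

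Non-coding RNA features outside the centromeres were more often lower in S7A. Among the features annotated neither as centromeric nor as antisense, a group formed after the values were seen, 47 of 95 tested were lower and 23 higher. Over the whole list fixed beforehand, centromeric RNAs included, 67 of 133 tested features were lower, 37 higher and 29 did not pass (68 lower and 37 higher when adjusted over the list alone), with a median log2 difference of -0.30. The list's camera call was marginal (adjusted p = 0.049). It was lost with quantile or median scaling (adjusted p = 0.056 and 0.055), with the replicate block (adjusted p = 0.053) and without either S2A array. It was also lost with an estimated correlation (adjusted p = 0.552). That estimate, -0.0031, was below the preset 0.01, so correlation between the genes was not the reason. The 4 members with the lowest p were SPNCRNA.231 and SPNCRNA.373, higher in S7A, and SPNCRNA.532 and prl11, lower. For prl11 the difference was at least 3.98-fold (log2 -0.64 with normexp).

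Heat shock protein genes were higher in S7A pink cells. Of the 16 tested, 12 were higher and none was lower, also when adjusted over the list alone, with a median log2 difference of 0.33. The small heat shock protein gene hsp16 was 7.86-fold higher (log2 difference 2.97 ± 0.18 SE, adjusted p = 0.000254), the Hsp70 gene ssa1 5.42-fold, the disaggregase gene hsp104 3.63-fold and the mitochondrial hsp78 1.91-fold. In the stress response list 16 of 26 genes were higher and 2 lower (17 and 3 when adjusted over the list alone). The calcium-transporting ATPase gene cta3 was at least 7.96-fold higher (log2 1.38 with normexp), ish1 2.78-fold and tms1 2.30-fold, whereas rds1 was 3.54-fold lower. Both lists passed camera with its preset correlation (adjusted p = 0.00118 and 0.0305). Neither passed with an estimated correlation (adjusted p = 0.552 for both), where almost no list could. The estimates, 0.316 and 0.029, were above the preset 0.01, so the preset p-values may be too small. Also among the 12 largest fitted increases was ecl1, a gene linked to chronological lifespan, at 13.4-fold (log2 2.95 with normexp). The antisense RNA SPNCRNA.574 was another, at no less than 2.92-fold (log2 0.81 with normexp). Its rank rests on S2A signal near background.

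Ribosomal protein genes differed little, and most did not pass. The median log2 difference of the 143 tested was -0.10, with 40 lower, 5 higher and 98 not passing (17 lower and 3 higher when adjusted over the list alone). Camera called the list (adjusted p = 0.000536), but not with quantile scaling (adjusted p = 0.191). Nor did it with an estimated correlation (adjusted p = 0.625), where almost no list could pass. That estimate, 0.364, was above the preset 0.01, so the preset p may be too small. Among its members with the lowest p, rpl3002 was 1.28-fold lower and rpl1603 was 1.38-fold higher. The other named members, rpp21 and rpp40, encode RNase P subunits that the name pattern also caught. The 43 ribosome biogenesis genes had a median of -0.02 (adjusted p = 0.466).

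Genes of the RNAi pathway, which processes centromeric transcripts into small RNAs, changed in both directions. Of the 13 tested, 6 were higher, 5 lower and 2 did not pass, with the same counts adjusted over the list alone (camera, adjusted p = 0.941). The RNA-directed RNA polymerase gene rdp1 was 1.68-fold lower in S7A, ers1 1.84-fold lower and dsh1 1.74-fold lower, and stc1, which links RNAi to chromatin modification, was 1.77-fold higher. The Dicer gene dcr1 was among the higher genes, but was not well above background on either S2A array and no size is given. Among 21 heterochromatin genes, 6 were higher and 11 lower (6 and 12 when adjusted over the list alone; camera, adjusted p = 0.346). The methyltransferase complex genes rik1 and cul4 were 1.84-fold lower and 1.92-fold higher, sir2 was 1.62-fold lower and taz1 1.37-fold lower. The gene for the heterochromatin protein Swi6 differed by 0.06 log2 (adjusted p = 0.291).

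Genes of the mating response also split. Among 21 tested, 11 were higher in S7A and 7 lower, with the same counts adjusted over the list alone (camera, adjusted p = 0.326). The transcription factor gene ste11 was 4.65-fold higher (log2 1.35 with normexp) and the kinase gene byr1 2.58-fold higher. The pheromone gene mfm2 was at least 2.17-fold higher (log2 0.61 with normexp). In contrast, the exchange factor gene ste6 was 2.17-fold lower and the agglutinin gene mam3 1.87-fold lower. Of the 3 tested genes on the plus-type list, matPc and map1 were higher and map4 was 1.95-fold lower (camera, adjusted p = 0.528). Of the 5 on the minus-type list, mat1-Mc, mfm2, map3 and mam1 were higher and mfm1 was lower (camera, adjusted p = 0.115). The gene map3 is annotated as the M-factor receptor gene and belongs with the plus type, so neither list holds its type exactly. For map1 no fold is given, since the bound against background was under 1. The gene map3 was at least 1.66-fold higher (log2 0.22 with normexp) and mam1 1.17-fold. Of these genes, mat1-Mc, matPc, mfm2, map1 and map3 passed the filter through S7A alone, which favours a higher value there. Counts adjusted over each of these lists alone were the same.

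**Figure D3:**
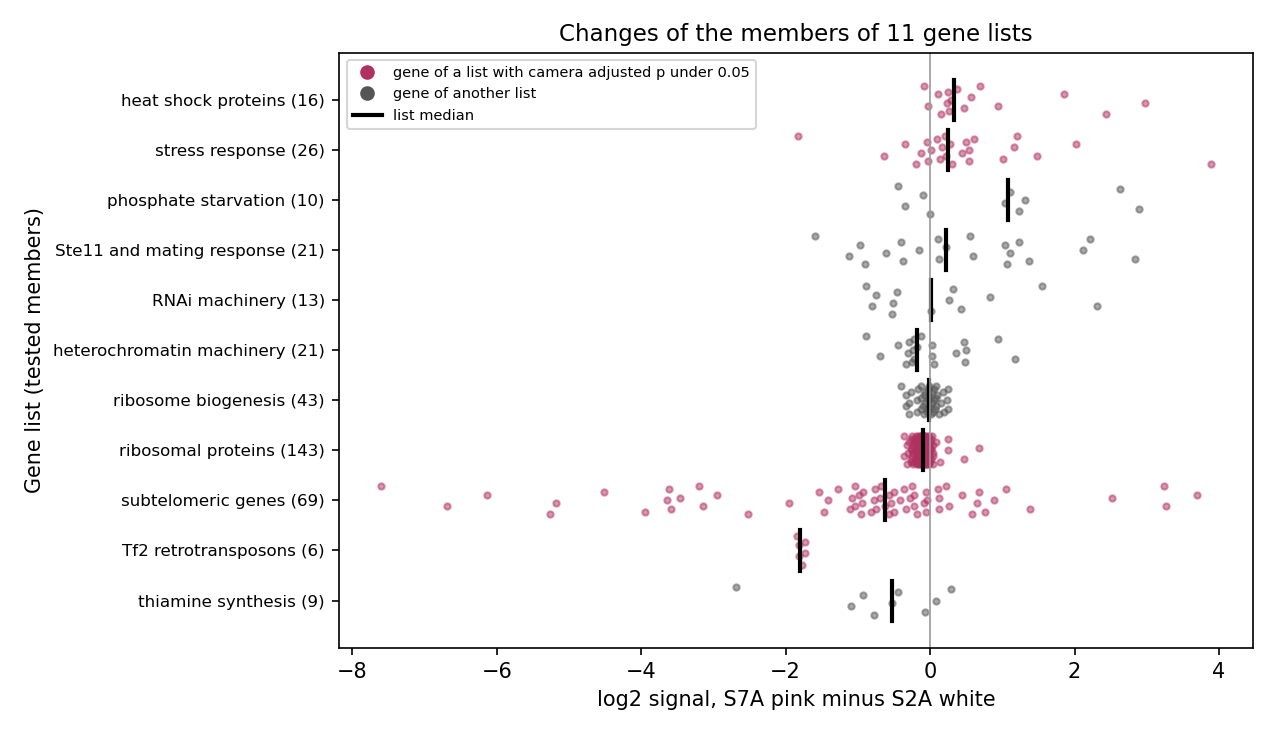
Log2 difference, S7A pink minus S2A white (horizontal axis), of every tested member of 11 gene lists (points) with the list median (black line); the number of members stands in brackets. Red lists passed camera with its preset correlation; Tf2 elements lie near -1.79 and heat shock genes reach 2.97.

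Marker genes used for auxotrophic selection were compared because laboratory strains often differ in them. Of 14 tested, 5 were higher in S7A and 1 lower, also when adjusted over the list alone (camera, adjusted p = 0.326). The largest difference was 1.61-fold, for ura4. The genes his7 and ura1 were 1.23-fold and 1.28-fold higher, and his2 was 1.30-fold lower.

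Across the genome, 2964 of 4893 tested genes (60.6%) passed an adjusted p of 0.05 in limma, with 1495 higher and 1469 lower in S7A pink cells. Which direction held more genes turned with the scaling: 1410 were higher and 1584 lower with quantile scaling, and 1640 and 1322 with the authors' value table. Most of these differences were small: 437 reached 2-fold, of which 276 were higher and 161 lower, and the median absolute log2 difference over all genes was 0.23. With the normexp background 158 genes passed and reached 2-fold. Of the 33 lists with at least 3 tested members, 6 passed camera with its preset correlation, 2 higher and 4 lower in S7A. None passed with an estimated correlation (smallest adjusted p = 0.552), a setting in which 4 arrays let almost no list pass. For the subtelomeric, Tf2, heat shock, stress and ribosomal protein lists the estimate lay above the preset, so their preset p may be too small. Groups of 2 arrays allow an exact permutation p no smaller than 0.333, so every p-value here rests on limma's pooled estimate of the spread. All 4 arrays lay on 1 slide, with the S2A arrays at neighbouring positions and the S7A arrays at the next positions, so array position and group cannot be told apart.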

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

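The number of genes differing between S7A pink and S2A white was 2964, and it stayed between 2780 and 3202 under other backgrounds, scalings, filters, variance models and the value table, all fixed beforehand. It was 2074 at an adjusted p under 0.01, and 1992 to 2897 without 1 array, where the lone array is assumed to vary like the other group. Of the genes called with all arrays, 1975 were also called without S7A pink replicate 1. A 2-fold minimum lowered it to 437, and 438 genes were 2-fold apart whatever the p, since a threshold on size is stricter by construction. With normexp 158 genes passed both limits; its offset of 50 pulls dim signals together by construction. The folds of 6 of 38 named genes measured in both groups shrank by over 1.5 times, and those of all 24 genes given as bounds fell under the bound. The replicate block gave 2791 genes and 5 lists. Same-numbered arrays showed no shared deviation (correlation of deviations 0.0164). Replicate differences were close to the spread between spots, so a pairing of the samples could go unseen. The count of lists, 6, became 12 with normexp and lay between 4 and 9 under the other scalings, filters and models. It also moved without 1 array, and the cause of these moves was not tested. With an estimated correlation it was 0 (also 0 at an unadjusted p under 0.05). In that setting the few residual degrees of freedom let almost no list pass. Fry, which sets no list against other genes, called 25. The ade6 difference of 0.11 kept its direction under every alternative (0.0705 to 0.152 without 1 array) and passed the threshold only with the variance trend (0.11, adjusted p = 0.049; range of adjusted p 0.049 to 0.283). No named gene changed direction, and of their values under the alternatives 852 kept their side of the threshold and 4 lost it, all of them mam1. Most named genes were picked for large or low-p differences on these same arrays, so this stability was close to fixed by the choice. The RNAi list, never past the threshold, had a median of -0.0403 with normexp, -0.0553 with quantile scaling, -0.459 for genes well above background on all 4 arrays, and -0.0830 (without S2A white replicate 1) to 0.196 (without S2A white replicate 2) with 1 array left out, against 0.01; the cause was not tested. With no filter on dim probes the plus and minus mating lists had medians of -0.466 and -0.0919, with more dim genes entering; the cause was not tested. Mean-of-probes and saturated-probe settings changed nothing, as each gene had 1 probe and no spot was saturated, and a slide block could not be fitted because the arrays lay on 1 slide. Signal over background limits the 636 untested genes and the folds given as bounds.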

Other observations

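Single genes of further groups differed between the mutants, although none of the lists in this part passed camera; the genes named were chosen after their values were seen. The tests on the centromeric RNAs and the chromosome 2 block were likewise chosen, and their bounds set, after those results were seen, whereas the test on neighbouring genes was set beforehand. Phosphate genes were mostly higher in S7A pink cells: of 10 tested, 6 were higher and 1 lower (6 and 2 when adjusted over the list alone), with a median log2 difference of 1.07 (camera, adjusted p = 0.115). The polyphosphate polymerase subunit gene vtc4 was 7.45-fold higher, the glycerophosphodiester transporter gene tgp1 6.19-fold, the acid phosphatase gene pho1 2.15-fold and the transporter gene pho84 2.05-fold. Outside that list, asp1, the inositol pyrophosphate kinase gene, was 9.39-fold higher. With the normexp background the log2 difference was 1.55 for tgp1 and 2.21 for asp1. Thiamine synthesis genes tended the other way, with 6 of 9 lower and 1 higher (camera, adjusted p = 0.076); nmt1, a thiamine-repressed gene, was 6.43-fold lower (log2 -1.18 with normexp). Of 10 iron acquisition genes 6 were lower and 2 higher, also when adjusted over the list alone (camera, adjusted p = 0.266), with fio1 2.88-fold and fip1 2.49-fold lower and no other member called at 2-fold. Among the antisense RNAs named as such by the array annotation, 26 were tested, 19 were lower in S7A and 3 higher. This group was formed after the values were seen and was not run through camera, and whether its probes read the antisense strand was not tested.

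Among the genes for the CTD's kinases and phosphatases, 6 of 10 were lower in S7A and 1 higher, also when adjusted over the list alone (camera, adjusted p = 0.157). The kinase gene lsk1 was 1.94-fold lower, the phosphatase gene fcp1 had a log2 difference of -0.53, and lsg1 was 1.77-fold higher. In the meiotic group regulated by Mmi1, 5 of 10 tested genes were lower and 2 higher (6 and 2 when adjusted over the list alone; camera, adjusted p = 0.224); rec10 and ssm4 were 3.19-fold and 3.13-fold lower, while mei2, a meiotic regulator outside that group, was 4.34-fold higher. With normexp the log2 difference was -0.58 for ssm4 and 1.09 for mei2. Of the 4 genes caught by the pattern for small nuclear and nucleolar RNAs, 1 was lower (camera, adjusted p = 0.362). By the colour assay white cells express the reporter more than pink cells, yet the centromeric RNAs were higher in the pink S7A cells and the ade6 signal did not differ past the threshold.

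The first pattern is the rise of centromeric RNAs in S7A relative to S2A. Median scaling and the value table moved most genes by a like small amount, so they were a weak test of scaling. With dim RNAs at their bounds, the lowest median over the scaling and value table alternatives was 3.62 log2. The choice among these scalings thus does not account for the rise. Nor does background subtraction for the 5 RNAs well above background on all 4 arrays, whose median with normexp was 3.49, past the bound of 2 set against it (SPNCRNA.232 alone was at 1.56 and SPNCRNA.483 was lower). For the 7 dimmer RNAs it stays open as a group: their median with normexp was 1.78, and 1.96 over all 12, between that bound and the bound under 1 set for it. Among the 7, SPNCRNA.360, SPNCRNA.231 and SPNCRNA.372 stayed above 2 (4.15, 3.46 and 2.14), and the lowest was at 0.40. Scaling and background had first been 1 test, split after its values were seen, and the tests by brightness were added later with the same bounds. Whether the raised probes read 1 long repeat also stays open: the 11 probes fell into 10 groups with no run of 20 bases in common, but probes at different points of a repeat would share none, and probes were not placed on a genome. Genotype and colony colour, and whether S7A raised or S2A lowered these RNAs, stay open without wild type.

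The second pattern is the block at the right end of chromosome 2, where 11 of 12 tested transcripts were near background in S7A. The genes outside the block had a median of -0.45, against -3.60 inside with dim genes at their bounds. The block was delimited by its own low values, and 11 of its tested genes passed the filter through S2A alone. A wide gap was thus close to fixed in advance. With normexp the named block genes lay between -3.33 (gal1) and -0.71 (gal10). The whole subtelomeric list, fixed beforehand, had a median of -0.63, or -0.41 with normexp. A fall shared by every subtelomeric gene is argued against, since 11 of the 58 tested outside were higher. Whether the block fell further than the genes around it cannot be judged from a block chosen this way. Loss of this DNA segment from the S7A strain is 1 candidate explanation. Without wild type, a fall in S7A cannot be told apart from a raised signal in S2A. On both S7A arrays 7 of the 11 dim probes lay above the 95th percentile of the negative control spots, but so did 40.2% of the 542 probes that were not well above background on any array (one-sided exact binomial p = 0.102). A first bound, at least 3 such probes with 1 block gene still measured, had been met and argued against loss. It was replaced after that was seen, because negative controls lie below many unexpressed probes. A lost segment and a silent one cannot be told apart from RNA; the 1 block gene still measured, SPBPB2B2.19c, shares probe sequence with ftm5 elsewhere.

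The third pattern is the joint rise of mat1-Mc and matPc. Both passed the filter through S7A alone, so their direction was close to fixed by it. With the normexp background they differed by 2.14 and 0.52 log2, both past the threshold. Strain mating type, release of the silent cassettes and the higher ste11 signal may each contribute; none was tested, and mating types of the strains are not given in the sources used here.

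One further hypothesis, written before its result was seen, was that neighbouring genes change together along the chromosome arms, as shared domains or transcription running into the next gene could produce. Over 4756 adjacent pairs, with subtelomeric and centromeric features left out, the Pearson correlation across genes was 0.0678 and Spearman's rho 0.0657 (permutation p = 1e-04 for each, the smallest that 10000 permutations can give). The relation is weak, genes are not independent replicates, and overlap of unannotated transcript ends was not tested.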
